A study of Sus scrofa with 77 samples.

How the data were processed

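Total RNA from scraped intestinal mucosa of boars was hybridised to 77 single-channel Agilent pig arrays, 38 from jejunum and 39 from ileum. Each array held the RNA of 1 pig and 1 tissue. The labels gave the tissue, the diet and a pig number, and every group was taken from these labels. The label of the dye was biotin, while the labelling kit named there was a one-colour kit, so each array was treated as one-colour data. Litter, which the study used for blocking, was not in the labels and could not enter any fit.

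The deposited scanner files came from Agilent Feature Extraction (version 10.7.3.1 for 69 arrays on 11 slides and version 11.5.1.1 for 8 arrays on 2 slides, the latter scanned on a second day). Per the file headers, their processed signal was an intensity with the local background subtracted and spatial trends removed, with no scaling between arrays. The median spot signal and the local background were deposited as intensity values without normalisation. The flags for outlier spots, saturation and signal well above background were deposited as other values, 0 or 1 for each spot. The deposited series table held log2 values that the authors had quantile normalised within each tissue, as the near equal medians of its arrays showed (6.41 to 6.43 in jejunum and 6.68 to 6.69 in ileum). The authors named limma in their processing notes without its version or the steps taken. The series table was used only as an alternative, because its tissues lay on separate scales. Its values correlated with the log2 scanner signal at 0.993 to 0.999 across the probes of each array, where probes are not independent replicates.

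The 43803 spots of an array that were not controls carried 43603 probes. Outlier spots were left out (546 over all arrays, 0.0162%). The processed signal of each array was divided by its 75th percentile and taken to log2. A probe was kept for a tissue when its signal was well above background on at least 6 arrays of that tissue. Probes were joined to genes through RefSeq accessions and a reference table on assembly Sscrofa11.1. Of 7111 probes with such an accession, 6686 matched a gene, which gave 2962 named genes. A further 8220 probes carried only an Ensembl transcript that could not be joined to a symbol. Where several probes shared a gene, the probe with the highest mean was used, which left 35867 features before filtering. Counts of changed features therefore include many without a gene symbol.

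The features of each tissue were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with diet as the factor, and each diet was compared with soybean meal, the reference diet. A moderated F test asked whether a feature differed among the 5 diets. All 77 arrays were fitted together for ileum against jejunum, averaged over diets, and for the 4 tests of whether a diet effect differed between tissues. Values of p were adjusted by the Benjamini-Hochberg method over all features of a comparison, and 0.05 was the threshold. Tests were two-sided, and errors given after a log2 difference are standard errors from these fits. Gene lists for pathways and cell types were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Of 40 lists with 758 genes, 352 genes were on the array, and 31 lists had at least 5 measured genes and were tested. Members of a list were also adjusted over the list alone. The lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The rule named, for each diet comparison, the 12 largest rises and 12 largest falls among genes with a symbol past the threshold. Where fewer than 3 genes passed in a direction, the 3 with the smallest p were given as values. For the tissue comparison it named 12 genes in each direction, for the F tests and the tissue by diet tests the 6 genes with the smallest p, and for each list past its threshold up to 4 members. Some genes that met the rule are not reported here. Features outside the rule are marked in the text as chosen after their values were seen.

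Equal pig numbers were taken to mark the same animal in both tissues. This was checked by correlating, over features, the deviations from the group means. The median correlation was 0.222 for the 38 equal numbers (lowest -0.053, highest 0.515) and -0.0019 for unequal numbers. Paired fits with the pig as a block were run as an alternative for the tissue comparison and the tissue by diet tests. Chromosome positions came from the same reference table. The fits were tested on simulated data, in which 200 features were shifted by log2 0.5, 1 or 2. Values were drawn at random around the mean of each feature with its real within-group SD, independently for each feature and array. Shifts of log2 1 were recovered for 59.5% to 68.5% of features in jejunum, 71.0% to 81.5% in ileum, 99.5% between tissues and 46.0% to 52.5% in the tissue by diet tests. With nothing shifted, 0 features passed in any of these limma fits. The simulated values held no slide effects and no correlation between features, so these rates need not hold for the real arrays.

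The alternatives were normexp background correction of the median spot signal (offset 50), quantile normalisation, no detection filter, every probe on its own, the slide as a fixed or a random block, array weights, a floor on low signals, the series table, and fits of the arrays of 2 diets only. Alternatives added after the data were seen left out the second scan day, the noisiest array, pigs 26 and 32, or single arrays in turn. The number of arrays per group limits the precision of every value. Tables and figures were made with the data.table package (1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.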

Results

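Gene expression was measured in mucosa scraped from the middle jejunum and the middle ileum of growing boars fed 1 of 5 diets that differed in their protein source. The sources were soybean meal, which served as the reference, black soldier fly, rapeseed meal, wheat gluten meal and spray dried plasma protein, a powder made from blood plasma. Each diet had 8 pigs in each tissue, except spray dried plasma protein with 6 in jejunum and 7 in ileum, and 38 pigs gave both tissues. Of 43603 probes, between 20593 and 32011 were well above background on an array. The 75th percentile of the signal lay between 430.4 and 1057 units per array. The arrays lay on 13 slides, of which 3 held both tissues. The slide accounted for 91.6% of the first principal component in jejunum and diet for 15.8%, so slide-blocked and within-slide values are given for the diet comparisons. Genes were named from these same arrays, so their signs across pigs or slides describe them and are not separate support.

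Spray dried plasma protein in place of soybean meal gave the most changed features in jejunum. The largest fall among named genes was in MEG3, an imprinted long noncoding RNA, at log2 -2.23 ± 0.59, followed by NPY, the neurotransmitter neuropeptide Y, at -1.66 ± 0.41 and CHRM1, a muscarinic acetylcholine receptor, at -1.56 ± 0.42. Their adjusted p were 0.0461, 0.0361 and 0.0484 (n = 6 against 8 pigs). CLDN5, the claudin of endothelial tight junctions on chromosome 14 at 51161490 to 51162382, fell by 1.505 ± 0.31 (adjusted p = 0.0141). CCL11, the eosinophil attractant eotaxin, fell by 1.49 ± 0.33. C7, a terminal complement component, fell by 1.47 ± 0.35 and MCT7, a mast cell tryptase, by 1.51 ± 0.35. PDLIM3, a muscle LIM domain protein, fell by 1.37 ± 0.26. CCR10, the receptor of the mucosal chemokine CCL28, fell by 1.34 ± 0.28, and BPI, a bactericidal protein, by 1.46 ± 0.38. ITIH4, a plasma protease inhibitor, fell by 1.41 ± 0.37, and PROCR, the endothelial protein C receptor, by 1.39 ± 0.35. A second kept probe of PROCR had the opposite sign. MEG3 was well above background on 3 of the 6 plasma protein arrays and on 8 of 8 soybean meal arrays.

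GUSB, the lysosomal beta-glucuronidase, rose 1.61-fold in jejunum with spray dried plasma protein (log2 0.69 ± 0.13, adjusted p = 0.01001), ARSA, the lysosomal arylsulfatase A, by log2 0.63 ± 0.16, and RENBP, an epimerase of acetylated amino sugars, by 0.80 ± 0.22. ACY1, which releases amino acids from their acetylated forms, rose 1.93-fold (log2 0.95 ± 0.25, adjusted p = 0.0461), and FITM1, a protein of lipid droplet formation, 1.84-fold (0.88 ± 0.20). PPARGC1A, a coactivator of mitochondrial genes, rose by 0.76 ± 0.19, and CDH1, the epithelial cadherin, by 0.49 ± 0.13. CCL3L1, a chemokine, rose by 0.83 ± 0.20, NMB, the neuropeptide neuromedin B, by 0.52 ± 0.12, and UGP2, which makes UDP-glucose, by 0.35 ± 0.10. All 23 genes that met the naming rule lay on the same side of the soybean meal mean in 6 of 6 pigs.

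Several fixed lists of cell types shifted down in jejunum with spray dried plasma protein. Of 6 measured endothelium genes, 4 fell over all genes and 5 when adjusted over the list alone. Among them were VWF, which binds platelets, at -1.19 ± 0.26, PECAM1 at -1.23 ± 0.27 and CDH5, the endothelial cadherin, at -1.13 ± 0.26 (list adjusted p = 2.56e-07, and adjusted p = 0.120 with an estimated correlation). Of 8 fibroblast and matrix genes, 2 fell over all genes and 8 when adjusted over the list alone. The matrix proteins LUM stood at -1.04 ± 0.27 and SPARC at -1.16 ± 0.31 (5.21e-09, and adjusted p = 0.123 with an estimated correlation). Of 14 complement genes, 3 fell over all genes and 12 when adjusted over the list alone. C3, the central component, stood at -0.80 ± 0.21 and SERPING1, the C1 inhibitor, at -0.86 ± 0.24 (3.28e-11, and adjusted p = 0.123 with an estimated correlation). None of 7 smooth muscle genes passed over all genes and 6 fell when adjusted over the list alone, with the myosin light chain MYL9 at -0.87 ± 0.24. The list had 3.25e-05 (adjusted p = 0.265 with an estimated correlation). The 5 genes of eosinophils and mast cells gave 4 falls adjusted over the list alone and 0 over all genes by limma. All 5 had negative values, with MS4A2, a chain of the IgE receptor, at -1.47 ± 0.48 (list 0.00191, adjusted p = 0.265 with an estimated correlation). In 12 genes of tight and adherens junctions CDH1 rose and CLDN5 fell over all genes, and 3 rose and 1 fell when adjusted over the list alone. OCLN, occludin, stood at 0.44 ± 0.15 (list 0.0265, adjusted p = 0.311 with an estimated correlation). The 9 brush-border and luminal peptidases all had positive values, with DPP4 at 0.25 ± 0.11, and none passed alone (list 0.0232, adjusted p = 0.311 with an estimated correlation).

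Enteroendocrine genes also shifted up, with 9 of 9 positive and CCK, cholecystokinin, at 0.48 ± 0.19 (0.0119, and adjusted p = 0.311 with an estimated correlation). Genes of the proximal small intestine did so with 8 of 8 positive (0.0419) and fatty acid oxidation genes with 12 of 12 (0.0265), both at adjusted p = 0.311 with an estimated correlation. Inflammation and antimicrobial defence genes shifted down, with PIGR at -0.89 ± 0.27 and 5 of 24 falling when adjusted over the list alone (0.00102, and adjusted p = 0.311 with an estimated correlation). Macrophage and dendritic cell genes shifted down with AIF1 at -0.47 ± 0.23 (0.0456, and adjusted p = 0.529 with an estimated correlation). Cell cycle genes did so with 9 of 9 negative (0.0419, and adjusted p = 0.643 with an estimated correlation) and ribosomal protein genes with 16 of 18 (0.00102, and adjusted p = 0.501 with an estimated correlation). Cholesterol synthesis genes shifted down in jejunum too, with MSMO1 at -0.70 ± 0.20 and 5 of 11 falling when adjusted over the list alone (8.98e-04, and adjusted p = 0.265 with an estimated correlation). The cholesterol list was negative on 3 of 4 slides (-0.63 to 0.19).

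In total 374 of 22700 features changed with spray dried plasma protein in jejunum, 144 up and 230 down, of which 58 had a symbol (11 up and 47 down). An unadjusted p under 0.05 by limma was seen for 3613 of 22700. Of 31 lists 15 shifted, 5 up and 10 down, and 13 of these held with the slide as a block, the lists lost being those of cell cycle and proximal small intestine. With the slide as a block 941 features passed, 370 of the 374 among them. GUSB then stood at 0.67 and CLDN5 at -1.55. On the 4 slides that held both diets, all 23 named genes had the same sign on each slide. They were named for their size on these same arrays, so this adds no separate support. Rises outnumbered falls with no detection filter (51 up and 33 down) and with array weights (159 up and 153 down). The count was 13 (11 up and 2 down) without the second scan day, which left 32 jejunum arrays (5 with spray dried plasma protein and 7 with soybean meal). There the 23 genes kept their direction but none passed (largest adjusted p 0.217, GUSB 0.62 with adjusted p = 0.0810). Leaving out only plasma protein pig 25, scanned on that day, gave 33 features, and leaving out only pig 31, scanned on the first day, gave 47. The count lay between 33 and 755 when single arrays were left out in turn. No list call held with an estimated correlation, the smallest adjusted p being 0.120.

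**Figure D1:**
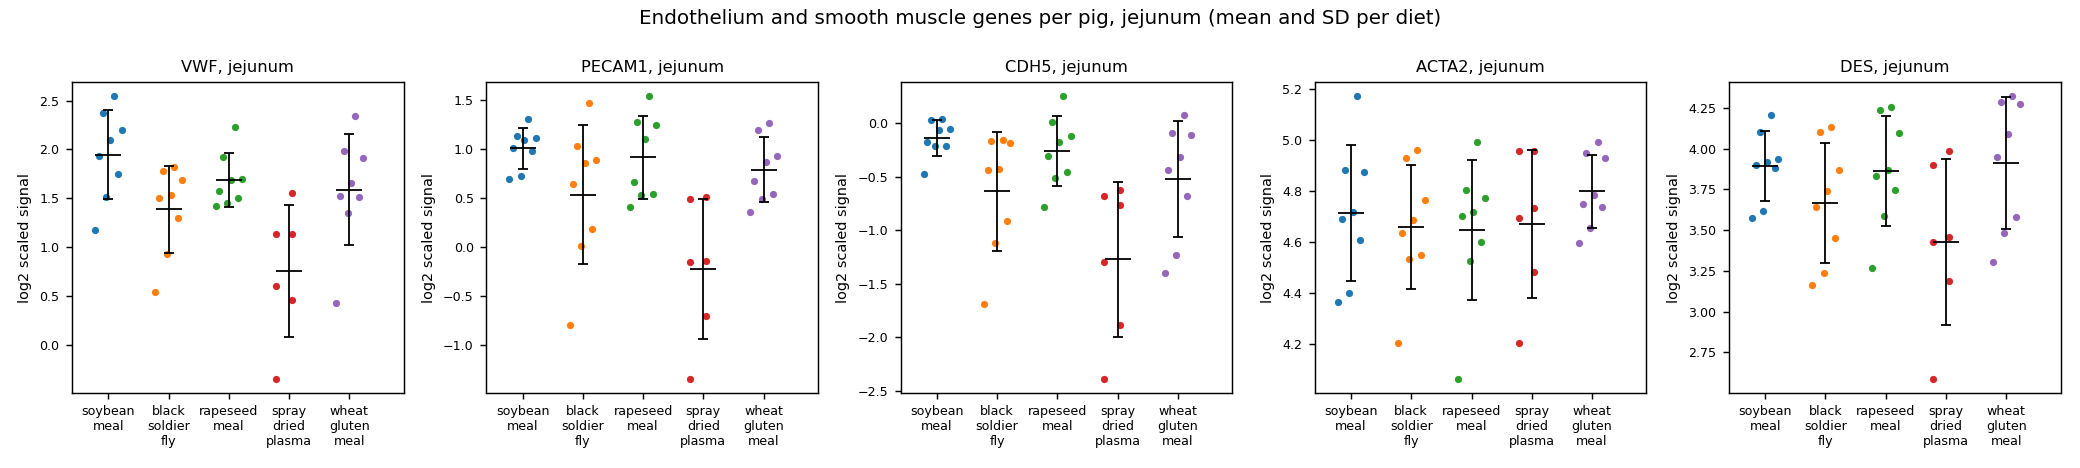
Log2 signal scaled to the 75th percentile of the array (y axis) of 3 endothelium genes (VWF, PECAM1, CDH5) and 2 smooth muscle genes (ACTA2, DES) in jejunum for each diet (x axis). Points are pigs, and lines give the mean and SD. VWF averaged 0.76 with spray dried plasma protein and 1.95 with soybean meal, DES averaged 3.42 and 3.89, and ACTA2 averaged 4.67 and 4.71.

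Spray dried plasma protein lowered genes of cholesterol synthesis in ileum as well, where single genes also passed over all genes. MSMO1, a sterol demethylation enzyme on chromosome 8 at 43726834 to 43745784, fell by 1.58 ± 0.24 (n = 7 against 8 pigs, adjusted p = 0.00255). CYP51, the lanosterol demethylase, fell by 1.25 ± 0.22 (adjusted p = 0.00495), and SQLE, squalene epoxidase, by 1.101 ± 0.21. INSIG1, the sterol sensor that restrains the pathway, fell by 1.27 ± 0.25, FDPS, which makes farnesyl diphosphate, by 0.91 ± 0.18 and NSDHL, a sterol dehydrogenase, by 0.83 ± 0.18. Of the 11 measured genes of this list, 7 fell over all genes, 4 did not pass, and 11 fell when adjusted over the list alone. The list's adjusted p was 7.81e-29, and adjusted p = 8.71e-04 with an estimated correlation.

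MT1A and MT3 rose in the same comparison. MT1A, a zinc and copper binding protein on chromosome 6 at 18672016 to 18673673, rose 6.66-fold (log2 2.74 ± 0.47, adjusted p = 0.00495) and MT3, of the same family, by 1.13 ± 0.23. CYP2B22, a cytochrome P450 of foreign compounds, rose by 1.80 ± 0.40 (adjusted p = 0.0437). CHRM1 fell by 1.79 ± 0.36 in ileum also (adjusted p = 0.0227), CCL28, a mucosal chemokine that attracts IgA cells, by 1.33 ± 0.27 and MMP3, a matrix protease, 2.14-fold (standard error of log2 0.24). The 13 genes that met the naming rule lay on the same side of the soybean meal mean in 7 of 7 pigs, or in 6 of 7 for CYP51, SQLE, FDPS and NSDHL.

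Of 8 fibroblast and matrix genes, 0 fell over all genes by limma and 7 when adjusted over the list alone. POSTN, periostin, stood at -1.18 ± 0.27 and LUM at -0.58 ± 0.15 (list 2.13e-11, and adjusted p = 0.0158 with an estimated correlation). Of 14 complement genes, 0 passed over all genes and 8 fell when adjusted over the list alone. CFB stood at -0.97 ± 0.23 and C5 at -0.76 ± 0.20 (6.05e-10, and adjusted p = 0.110 with an estimated correlation). In 25 genes of inflammation and antimicrobial defence 0 passed over all genes and 4 fell when adjusted over the list alone. PIGR, which carries IgA across the epithelium, stood at -1.41 ± 0.37, DUOX2, a source of hydrogen peroxide, at -2.59 ± 0.80 and REG3G, an antimicrobial lectin, at -3.06 ± 1.00 (2.05e-06, and adjusted p = 0.168 with an estimated correlation). Among 12 genes of the NRF2 and glutathione list 3 fell and 1 rose when adjusted over the list alone. GPX2, a glutathione peroxidase of the gut, stood at -1.50 ± 0.36 (0.00666, and adjusted p = 0.115 with an estimated correlation). Smooth muscle genes shifted down with DES, desmin, at -0.49 ± 0.17 (3.08e-06, and adjusted p = 0.138 with an estimated correlation), and endothelium genes with VWF at -0.49 ± 0.19 (0.00258, and adjusted p = 0.138 with an estimated correlation). Absorptive enterocyte genes shifted up, with FABP2, a fatty acid carrier, at 1.06 ± 0.25 (0.0133, and adjusted p = 0.339 with an estimated correlation).

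Over all features 37 of 22507 changed in ileum, 17 up and 20 down, of which 13 had a symbol (3 up and 10 down). An unadjusted p under 0.05 by limma was seen for 2016 of 22507, against 2568 with wheat gluten meal in ileum. Of 31 lists 15 shifted, 4 up and 11 down. Blocking by slide gave 59 features, 34 of the 37 among them, with MSMO1 at -1.60 and MT1A at 2.66. CYP2B22 no longer passed (adjusted p = 0.0642). On the 5 slides with both diets each of the 13 genes kept its sign, all 15 lists held with the slide as a block and 2 with an estimated correlation, and 31 features passed without the second scan day. The count lay between 7 and 79 when single arrays were left out in turn, and it was 10 with only the arrays of the 2 diets.

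**Figure D2:**
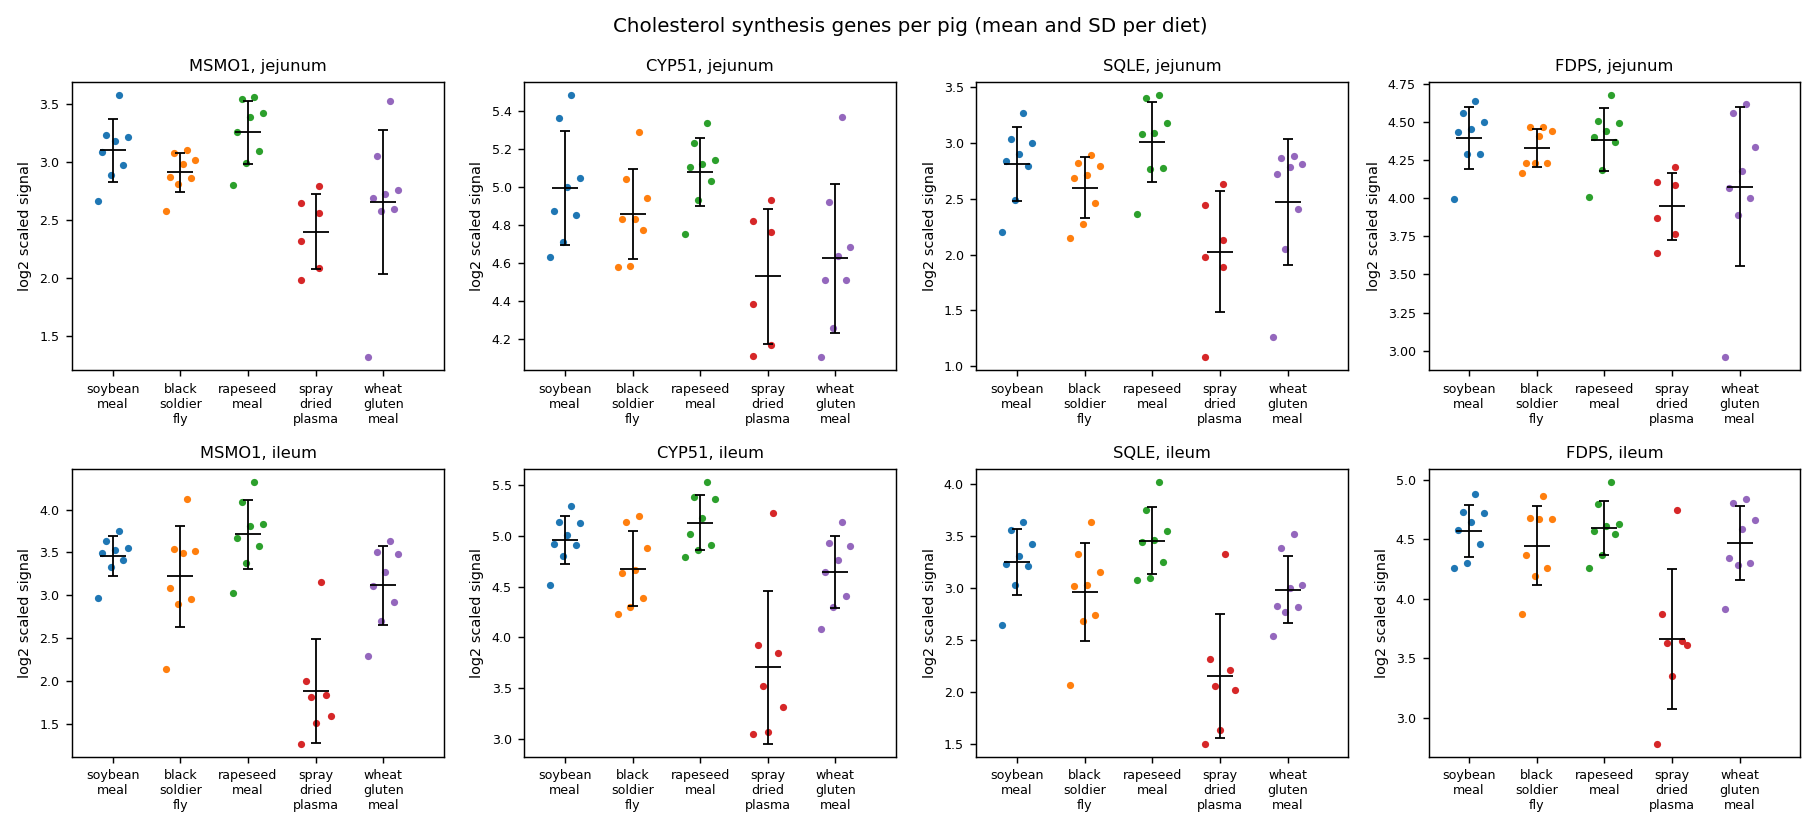
Log2 scaled signal (y axis) of MSMO1, CYP51, SQLE and FDPS for each diet (x axis) in jejunum (top) and ileum (bottom). Points are pigs, and lines give the mean and SD. In ileum MSMO1 averaged 1.88 with spray dried plasma protein and 3.46 with soybean meal, and plasma protein pig 4 stood apart at 3.16.

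Wheat gluten meal raised MT1A in ileum 4.94-fold (log2 2.31 ± 0.45, n = 8 against 8 pigs, adjusted p = 0.0447), with values above the soybean meal mean in 8 of 8 pigs. This call did not hold with the slide as a block (adjusted p = 0.5258), and it held in 3 of 16 fits with single arrays left out. ACY1 had a value of 0.75 ± 0.17 (adjusted p = 0.105) and FBXL4, a mitochondrial F-box protein, 0.85 ± 0.19, neither past the threshold. The DNA helicase BLM had -0.63 ± 0.14, the survival factor BCL2L1 -0.67 ± 0.17 and the mitotic phosphatase CDC25C -0.64 ± 0.17, also not past it. Of 9 cell cycle genes, 0 passed over all genes by limma and 7 fell when adjusted over the list alone. CCNB1, cyclin B1, stood at -0.52 ± 0.16 and BIRC5, survivin, at -0.50 ± 0.16 (list 3.25e-06, and adjusted p = 0.287 with an estimated correlation). All 5 measured genes of sugar digestion and transport rose when adjusted over the list alone and none over all genes. The glucose transporter SLC5A1 stood at 0.33 ± 0.12 and PCK1, of gluconeogenesis, at 1.19 ± 0.46 (1.09e-04, and adjusted p = 0.126 with an estimated correlation). Fatty acid oxidation genes shifted up, with the dehydrogenase ACADL at 0.36 ± 0.09 (1.61e-04, and adjusted p = 0.126 with an estimated correlation). Genes of xenobiotic metabolism shifted up with the efflux pump ABCG2 at 0.55 ± 0.15 and the nuclear receptor NR1I3 at 0.83 ± 0.23 (2.17e-04, and adjusted p = 0.126 with an estimated correlation). B cell genes shifted down with MS4A1, the CD20 antigen, at -1.16 ± 0.54 (0.0147, and adjusted p = 0.613 with an estimated correlation).

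With the slide as a block 4 of these 5 lists held and that of B cells did not. Within slides the cell cycle list was negative on 3 of 4 (-0.83 to 0.15) and the B cell list on 3 of 4 (-0.59 to 0.19).

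In all 5 features passed in ileum with wheat gluten meal, all up, and 2568 of 22507 had an unadjusted p under 0.05. The features other than MT1A have no symbol here and were chosen after their values were seen: AK346233 at 1.95 ± 0.33, TC569025 at 1.22 ± 0.23, AK344774 at 0.91 ± 0.17 and TC548059 at 0.62 ± 0.12. With the slide as a block 1 feature passed and MT1A stood at 1.96. On 3 of the 4 slides with both diets MT1A was higher with wheat gluten meal (from -0.56 to 2.95). The count was 0 without the second scan day (MT1A 2.20, adjusted p = 0.203), 2 without pigs 26 and 32 (MT1A adjusted p = 0.00557), and between 0 and 25 when single arrays were left out.

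In jejunum 0 features passed with wheat gluten meal in limma, with 1038 of 22700 at an unadjusted p under 0.05. The values of smallest p were KLF15, a transcription factor of amino acid and glucose metabolism, at 0.62 ± 0.18, MT1A at 1.88 ± 0.55 and DUSP6, a phosphatase of MAP kinases, at 0.57 ± 0.17. On the negative side they were HSDL2 at -0.38 ± 0.11, MCT7 at -1.05 ± 0.32 and C5 at -0.70 ± 0.22 (adjusted p = 0.969 for each, and 0.362 or more with the slide as a block). Each kept its sign on 6 of 6 shared slides. Complement genes shifted down, with 4 of 14 falling when adjusted over the list alone and 0 over all genes, among them CFB at -0.74 ± 0.24 (list 0.00704, and adjusted p = 0.787 with an estimated correlation). Inflammation and antimicrobial defence genes shifted up, with TNFAIP3, a brake on NF-kappaB, at 0.52 ± 0.18 (8.92e-04, and adjusted p = 0.688 with an estimated correlation). B cell genes shifted up (1.34e-04, and adjusted p = 0.638 with an estimated correlation) and cholesterol synthesis genes down, with HSD17B7 at -0.46 ± 0.15 (0.00187, and adjusted p = 0.688 with an estimated correlation). All 4 lists held with the slide as a block. The B cell list was positive on 4 of 6 slides (-0.60 to 1.40), and each of the other 3 had its sign on 5 of 6.

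Rapeseed meal gave 0 features past the threshold in jejunum and in ileum by limma, with 553 of 22700 and 1351 of 22507 at an unadjusted p under 0.05. The largest value in both tissues was that of CYP1A1, the cytochrome P450 induced through the aryl hydrocarbon receptor, on chromosome 7 at 58802887 to 58809155. CYP1A1 stood at 3.33 ± 0.98 in jejunum (higher in 7 of 8 pigs, adjusted p = 1.00 by limma) and at 4.24 ± 1.03 in ileum (higher in 8 of 8 pigs, adjusted p = 0.798). It had a positive sign on 5 of 5 slides in each tissue and stood at 3.24 and 4.09 with the slide as a block, where 0 features passed in either tissue. Other values of smallest p in jejunum were IFNE, an epithelial interferon, at 0.62 ± 0.16, JAK2, a cytokine receptor kinase, at 0.33 ± 0.09, LIMK2 at -0.26 ± 0.09, KLF8 at -0.31 ± 0.12 and NPY at -0.92 ± 0.38. In ileum they were RTN4, a protein of the endoplasmic reticulum, at 0.45 ± 0.11, PMM1, a phosphomannomutase, at 0.51 ± 0.14, MAP3K21 at -0.62 ± 0.21 and NOG, a BMP antagonist, at -0.77 ± 0.26 (adjusted p = 0.798 for each). On 1 of 5 slides the sign was opposite for KLF8 and NPY in jejunum and for RTN4, MAP3K21 and NOG in ileum.

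In jejunum 22 of 24 genes of inflammation and antimicrobial defence had positive values with rapeseed meal and none passed alone. Among them were REG3G at 1.90 ± 0.92 and LTF, lactoferrin, at 0.80 ± 0.37 (list 1.44e-04, and adjusted p = 0.420 with an estimated correlation). T and NK cell genes shifted down with CD3D at -0.36 ± 0.20 (0.0135, and adjusted p = 0.601 with an estimated correlation) and were negative on 3 of 5 slides (-0.67 to 0.17). Of the 4 lists of this comparison, 2 held with the slide as a block. In ileum 8 lists shifted, all up, of which 5 held with the slide as a block and 3 with quantile normalisation. Of 12 lipid absorption genes 11 had positive values, with SAR1B, of chylomicron transport, at 0.23 ± 0.08, and none passed (0.00200, and adjusted p = 0.296 with an estimated correlation). Sugar genes shifted up with PCK1 at 1.31 ± 0.46, the only one of 5 to rise when adjusted over the list alone (0.00558, and adjusted p = 0.382 with an estimated correlation). Peptide and amino acid transporters did so with SLC3A1 at 0.50 ± 0.21 and SLC15A1, the peptide transporter, at 0.32 ± 0.21 (0.0256, and adjusted p = 0.296 with an estimated correlation). Each of these lists was positive on 4 of 5 slides (lipid absorption -0.21 to 0.49, sugar -0.41 to 0.55 and transporters -0.09 to 0.31). Without pigs 26 and 32, 1 feature passed in jejunum and 3 in ileum. In both tissues pig 26 had the highest CYP1A1 of wheat gluten meal and pig 32 the lowest of rapeseed meal. The pigs were left out because of these values, so the counts are no separate support.

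**Figure D3:**
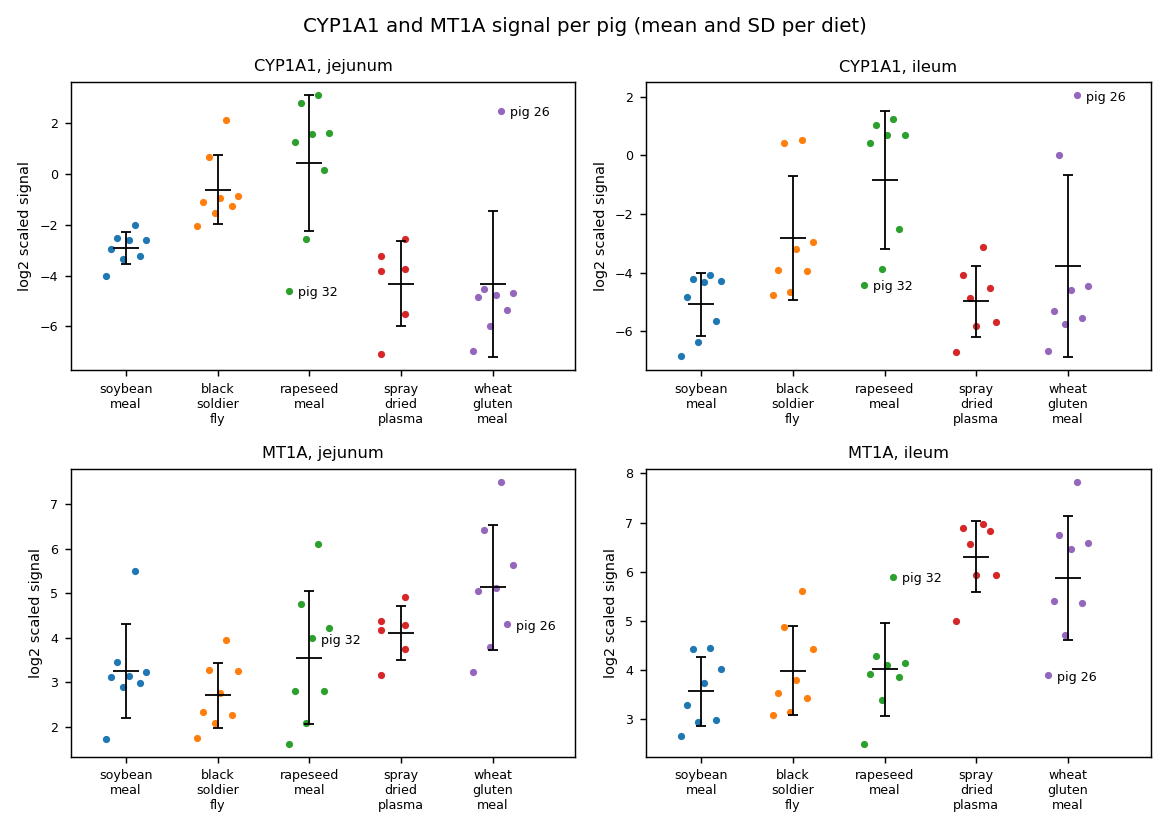
Log2 scaled signal (y axis) of CYP1A1 (top) and MT1A (bottom) for each diet (x axis) in jejunum and ileum. Points are pigs, lines give the mean and SD, and pigs 26 and 32 are marked. In CYP1A1, wheat gluten meal pig 26 stood at 2.50 in jejunum and 2.05 in ileum, and rapeseed meal pig 32 at -4.60 and -4.41.

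Black soldier fly gave 0 features past the threshold in either tissue by limma, with 2138 of 22700 at an unadjusted p under 0.05 in jejunum and 645 of 22507 in ileum. NPY had the values -1.21 ± 0.38 in jejunum and -1.05 ± 0.33 in ileum and lay below the soybean meal mean in 8 of 8 pigs in each (adjusted p = 0.515 and 1.00). In jejunum the other values of smallest p were DNAJB1, a heat shock cochaperone, at 0.41 ± 0.12, ACADL at 0.37 ± 0.11, CASP8, an initiator caspase, at 0.36 ± 0.11 and SLC22A4, a carnitine and ergothioneine transporter, at -0.64 ± 0.21 (adjusted p = 0.515 for each). SLC22A4 stood at -0.42 with the slide as a block and was then the 1 feature past the threshold (adjusted p = 0.0102). These genes kept their sign on 5 of 5 slides. In ileum the values of smallest p were AGPAT4 at 0.60 ± 0.19 and the lymphocyte antigens CD96 at 0.49 ± 0.16 and CD8A at 0.55 ± 0.18, each with the same sign on 4 of 4 slides (adjusted p = 1.00 with and without the slide block). IL4, MAP3K21 and, in jejunum, C13H21orf62 were near background on most fly arrays (well above it on 1, 3 and 2 of 8), so no value is given.

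Of 31 lists, 6 shifted in jejunum (5 up and 1 down) and 12 in ileum (4 up and 8 down) with black soldier fly, and no member passed over all genes. With the slide as a block 5 and 9 of these lists held. T and NK cell genes shifted up in both tissues, with 14 of 16 positive in jejunum (0.00657, and adjusted p = 0.509 with an estimated correlation). In ileum 11 of 16 were positive and the granzyme GZMA stood at 0.54 ± 0.20 (3.06e-05, and adjusted p = 0.240 with an estimated correlation). Within slides this list was positive on 3 of 5 in jejunum (-0.16 to 0.29) and on 2 of 4 in ileum (-0.11 to 0.40). Endothelium genes shifted down in jejunum with 6 of 6 negative and VWF at -0.56 ± 0.24 (0.0379, and adjusted p = 0.627 with an estimated correlation). In ileum smooth muscle genes shifted down with 7 of 7 negative and CNN1, calponin, at -0.35 ± 0.14 (2.55e-06, and adjusted p = 0.240 with an estimated correlation). Fibroblast genes did so with POSTN at -0.65 ± 0.26 (1.30e-04, and adjusted p = 0.240 with an estimated correlation). Fatty acid oxidation genes shifted up in both, with ACADL in ileum at 0.25 ± 0.09 (0.00657 in jejunum and 0.00210 in ileum, and adjusted p = 0.509 and 0.240 with an estimated correlation).

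**Figure D4:**
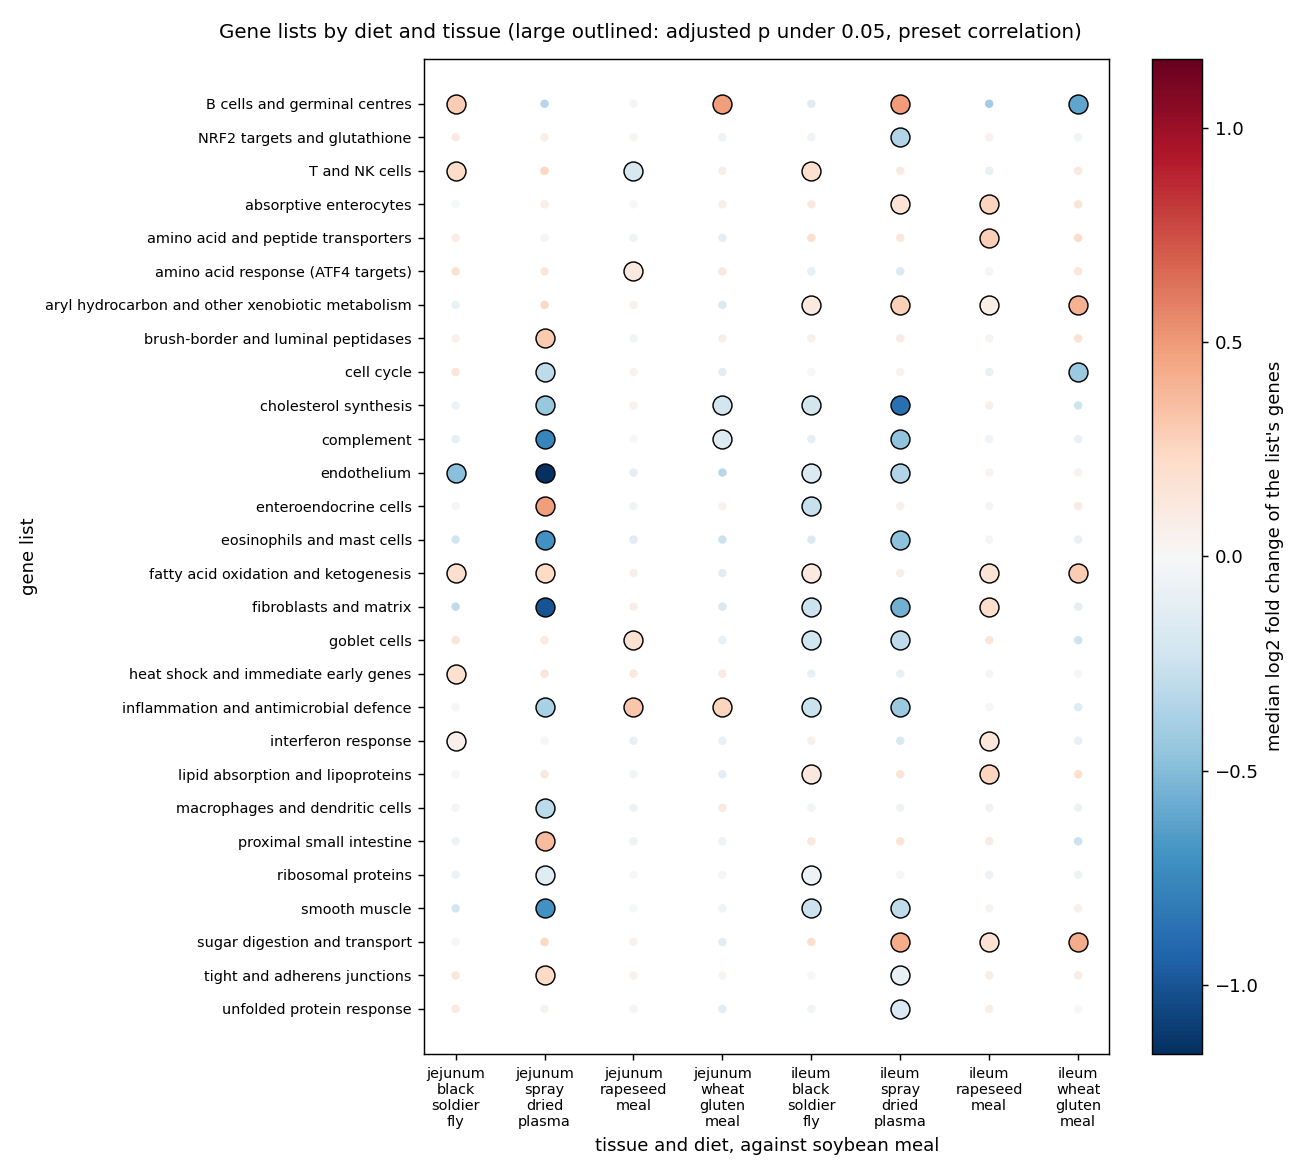
Median log2 difference from soybean meal (colour) of the genes of each list (rows) for each tissue and diet (columns), for lists that passed in at least 1 column. Large outlined circles mark an adjusted p under 0.05 with the preset correlation. The lowest median was that of endothelium in jejunum with spray dried plasma protein, at -1.16.

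Across the 5 diets, 59 of 22507 features differed in ileum by the F test, 21 with a symbol. MSMO1 (adjusted p = 0.00144), MT1A (0.00336), MT3 (0.00415) and CYP51 (0.00434) were among the 6 named genes, and their largest differences from soybean meal were those of spray dried plasma protein. SLC10A2, the ileal bile acid importer, also differed (adjusted p = 0.00433), with -0.80 for spray dried plasma protein and 0.49, 0.59 and 0.45 for black soldier fly, rapeseed meal and wheat gluten meal. None of these SLC10A2 differences from soybean meal passed alone (adjusted p = 0.127 or more by limma). In jejunum 21 of 22700 features differed, and CYP1A1 was the only one with a symbol (adjusted p = 0.0403), with 2.29 for black soldier fly, 3.33 for rapeseed meal and -1.42 for spray dried plasma protein. None of these CYP1A1 differences passed alone either (adjusted p = 0.515 or more by limma). CYP1A1 was well above background on 2 of 8 wheat gluten meal arrays in jejunum, on 5 of 6 with spray dried plasma protein and on 8 of 8 with each other diet, so no value is given for wheat gluten meal. PDLIM3, FRZB, GUSB and MT3 did not pass (adjusted p = 0.0510 to 0.0531). Blocking by slide gave 106 features in jejunum and 35 in ileum, 17 and 24 of them shared, and without the second scan day 0 and 37 passed.

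Ileum and jejunum differed in 15680 of 23407 features, 7481 higher and 8199 lower in ileum (n = 39 against 38 arrays), of which 1931 had a symbol (878 and 1053). The balance was 8394 higher and 7214 lower with quantile normalisation, and 7509 and 13639 with no detection filter. SULT1E1, which sulfates oestrogens, was 242-fold higher in ileum (log2 7.92 ± 0.17), FABP6, the ileal bile acid binding protein, 141-fold (7.14 ± 0.40), and SLC10A2 25.1-fold (4.65 ± 0.16). MS4A1 stood at 5.19 ± 0.32 and VPREB1, of the surrogate light chain of B cell precursors, at 5.42 ± 0.30. SPP1, osteopontin, stood at 5.98 ± 0.24, ZP3 at 5.79 ± 0.32, C3H2orf40 at 5.28 ± 0.30, MMP12, the macrophage elastase, at 4.84 ± 0.40 and PAEP at 4.23 ± 0.32. ATP1B4 was at least 24.4-fold higher, since no jejunum array had it well above background. BCO1, which cleaves beta-carotene, was lower in ileum at -6.61 ± 0.20, S100G, an intestinal calcium binding protein, at -6.50 ± 0.44, and TMPRSS15, the enteropeptidase that activates trypsinogen, at -5.96 ± 0.12. The lipoprotein gene APOC3 (-5.58 ± 0.19), the retinol carrier RBP2 (-4.48 ± 0.17), the transcription factor GATA4 (-4.63 ± 0.14) and the hormone motilin, MLN (-3.47 ± 0.18), were lower too. So were the water channel AQP10 (-5.66 ± 0.18), CYP2B22 (-5.01 ± 0.30), AKR1C1 (-4.84 ± 0.28) and the transporters SLC22A13 (-4.33 ± 0.21) and SLC5A4 (-4.21 ± 0.14). The largest adjusted p of the 24 genes that met the naming rule was 1.03e-17, and each lay on one side of the jejunum mean in 39 of 39 ileum arrays. In the tissue of lower signal, SULT1E1, ZP3, MMP12, PAEP, BCO1, AKR1C1, GATA4, SLC22A13 and MLN were near background on most arrays (well above it on 1 to 18), so their differences rest on signals near background.

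All 8 measured genes of the proximal small intestine were lower in ileum, among them CCK, cholecystokinin, at -2.21 ± 0.08 (list 2.69e-09, and adjusted p = 6.84e-05 with an estimated correlation). All 9 absorptive enterocyte genes were lower, with the fatty acid carrier FABP1 at -3.06 ± 0.17 (6.44e-09, and adjusted p = 0.0185 with an estimated correlation). Of lipid absorption genes, 10 of 12 were lower and 1 higher, with DGAT2, of triglyceride synthesis, at -3.18 ± 0.13 (1.36e-08, and adjusted p = 0.0135 with an estimated correlation). All 7 B cell genes were higher, with CD79A at 2.21 ± 0.16 (7.69e-06, and adjusted p = 0.0909 with an estimated correlation). The B cell list was positive on 2 of 3 slides (-0.12 to 1.76). Of 9 brush-border and luminal peptidases 7 were lower and 1 higher, with ACE at -2.17 ± 0.09 (3.88e-04, and adjusted p = 0.0909 with an estimated correlation). In inflammation and antimicrobial defence 16 of 25 were higher and 4 lower, with the defensin DEFB1 at 2.40 ± 0.12 (0.0129, and adjusted p = 0.384 with an estimated correlation). Of 31 lists 21 shifted, 8 up and 13 down, 16 held with the slide as a block, and the first 3 named here held with an estimated correlation.

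Because only 3 slides held both tissues, 2468 features passed with the slide as a fixed block, 2460 of them shared, and 12913 with the slide as a random block. Tissue and slide went closely together (association 0.947). Within these 3 slides 20 of the 24 genes kept one sign, and C3H2orf40, MS4A1 and PAEP were among those that did so on 2. On each of these slides at least 1 tissue had only 1 array, so these signs rest on few arrays. With the fixed block SULT1E1 stood at 8.41 and MMP12, at 3.09, no longer passed (adjusted p = 0.107). Pairing the tissues by pig gave 16299 features, and 15592 passed without the second scan day.

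The diet effect differed between tissues in 7 of 23407 features for spray dried plasma protein (2 up and 5 down in ileum relative to jejunum), in 1 for rapeseed meal and in 0 for black soldier fly and wheat gluten meal by limma. At an unadjusted p under 0.05 there were 2010, 476, 365 and 1549. None of the 8 has a symbol here, and those given were chosen after their values were seen. For spray dried plasma protein TC618497 differed by 1.20 ± 0.24, TC564756 by 1.07 ± 0.22, A_72_P322803 by -2.37 ± 0.50 and BM190451 by -1.12 ± 0.24 (adjusted p = 0.0451 for each), and for rapeseed meal A_72_P133471 by -1.58 ± 0.28 (adjusted p = 0.00990). BDNF, a nerve growth factor, had the smallest p of the named genes for spray dried plasma protein and did not pass (adjusted p = 0.0634). It was well above background on 2 of 6 plasma protein arrays in jejunum, so no value of this fit is given, and that of the paired fit, given below, rests on signals near background. Other values of smallest p were CKM at -0.90 ± 0.23, FITM1 at -1.01 ± 0.27, PDK1 at 0.78 ± 0.22 and BCL10 at -0.44 ± 0.13 for spray dried plasma protein (adjusted p = 0.146 to 0.213). For wheat gluten meal they were BCL2L1 at -1.27 ± 0.30, NMB at -0.57 ± 0.15, G6PC, the glucose-releasing phosphatase, at 2.22 ± 0.59, PDHB at 0.32 ± 0.10, SSTR5 at 1.01 ± 0.31 and HSDL2 at 0.48 ± 0.15 (adjusted p = 0.453 to 0.605). For rapeseed meal NOG stood at -1.14 ± 0.39 and LRP8 at -1.001 ± 0.36. For black soldier fly DNAJB1 stood at -0.51 ± 0.18, ATF4 at -0.46 ± 0.17 and UBE2D3 at -0.35 ± 0.14 (adjusted p = 1.00 for each). RHCG, S100A9, EXTL2 and CSRP3 for rapeseed meal and RHCG, GDF5 and PRM1 for black soldier fly were near background on most arrays of at least 1 group, so no value is given.

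Cholesterol synthesis genes had the lowest adjusted p of the tissue by diet list tests for spray dried plasma protein, with 11 of 11 values more negative in ileum. Of these, 7 were past the threshold when adjusted over the list alone and 0 over all genes, among them INSIG1 at -1.18 ± 0.38 (list 1.29e-08, and adjusted p = 0.160 with an estimated correlation). Endothelium genes went the other way, with 6 of 6 positive, 4 past the threshold when adjusted over the list alone and CDH5 at 0.78 ± 0.28 (8.47e-04, and adjusted p = 0.219 with an estimated correlation). For wheat gluten meal 5 of 7 B cell genes passed as negative when adjusted over the list alone, with MS4A1 at -2.85 ± 1.00 (3.69e-06, and adjusted p = 0.115 with an estimated correlation). Of sugar genes 2 of 5 passed as positive, with G6PC and PCK1 at 1.95 ± 0.62 (1.05e-04, and adjusted p = 0.115 with an estimated correlation). With the slide as a block 28 features passed for spray dried plasma protein, 1 for rapeseed meal and 0 for the other diets, and pairing by pig gave 14, 1, 0 for black soldier fly and 1 for wheat gluten meal. Only 3 slides held both tissues, too few for within-slide values of these differences, and without the second scan day 0 features passed for spray dried plasma protein and 1 for rapeseed meal.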

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

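The tests of slides and scrapings for the stromal genes, and of slides and enterocytes for the cholesterol genes, were chosen only after the result was seen. Those of scan days and of pigs 26 and 32 were written down before they were run.

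In jejunum with spray dried plasma protein the genes of endothelium, fibroblasts, complement and smooth muscle were lower as a set, with a mean over 35 genes of -0.81 ± 0.196 (interval -1.20 to -0.41). Members did not all fall alike, and ACTA2 of smooth muscle averaged 4.67 against 4.71 with soybean meal. The slides did not produce the lower mean of the set, since it was -0.807 with the slide as a block. The second scan day was not its whole cause, since the mean was -0.759 (interval -1.21 to -0.30) without it. Scrapings that held less of the deeper wall were taken to lower smooth muscle and stroma alike. Smooth muscle stood at -0.58, fibroblasts at -1.04 and endothelium at -0.95. The difference of smooth muscle from the mean of the other 2 was 0.416 (interval 0.21 to 0.62), so the lists did not fall equally. A loss of cells need not lower each list by the same amount, so less of the deeper wall, equal or uneven, is not excluded.

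In ileum with spray dried plasma protein the 11 cholesterol synthesis genes had a mean of -0.92 ± 0.149 (interval -1.23 to -0.62). With the slide as a block it was -0.94, so slides did not produce it. Absorptive enterocyte genes had a mean of 0.30 (interval -0.07 to 0.67), so a loss of enterocytes that lowers both lists alike was not seen. The 9 genes of that list can themselves change with diet, so a change in the mix of cells is not excluded.

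CYP1A1 of wheat gluten meal pig 26 was 2.50 in jejunum, where the next pig of its diet had -4.52, and 2.05 in ileum. Rapeseed meal pig 32 had -4.60 and -4.41. If the diets of these pigs had been exchanged, 50 other genes should place their arrays nearer the other diet, and 4 of 4 arrays were. Among the other pigs of these diets 22 of 28 arrays lay nearer their own diet and 6 nearer the other (10 and 4 in jejunum, 12 and 2 in ileum). In jejunum rapeseed meal pig 12 lay about as far toward the other diet as pig 32. Wheat gluten meal pigs 46 and 5 lay further toward it there than pig 26. Only CYP1A1, MT1A and MSMO1 were kept out of the 50 genes, so genes that follow CYP1A1 may be among them. An exchange of the labels is therefore possible and was not shown, and no label was changed.

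In CYP51 (5.22, next 3.93) and MSMO1 (3.16, next 1.99), spray dried plasma protein pig 4 was the highest of its group in ileum. In jejunum BPI of soybean meal pig 42 was 4.35 (next 3.50), and PPARGC1A of soybean meal pig 8 was 2.14 (next 2.79). PDLIM3 of spray dried plasma protein pig 31 was -3.80 in jejunum (next -2.43). In ileum MT3 of rapeseed meal pig 32 was 3.37 (next 2.48), and SLC10A2 of wheat gluten meal pig 46 was 3.84 (next 4.67). The tissue by diet tests gave 7 features for spray dried plasma protein and 1 for rapeseed meal, and BDNF passed only with the pairing by pig, at 1.69 (adjusted p = 0.0162), a value that rests on signals near background, since 2 of 6 plasma protein arrays in jejunum had it well above.

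The 75th percentile of the signal was 1051 in ileum of black soldier fly pig 11 and 824 in jejunum of rapeseed meal pig 1. Jejunum of wheat gluten meal pig 37 had 20593 probes well above background, and its negative controls had a mean of 70.4 and an SD of 21.6. The mean of negative controls was 60.2 in ileum of rapeseed meal pig 18 and 54.0 in ileum of spray dried plasma protein pig 31, where the SD was 9.08. That SD was 5.78 in ileum of soybean meal pig 29, 6.42 in jejunum of soybean meal pig 42 and 10.05 in jejunum of black soldier fly pig 3. Jejunum of spray dried plasma protein pig 36 had 1 saturated probe. Outlier spots numbered 23 in ileum of black soldier fly pig 33 and 29 in ileum of wheat gluten meal pig 26. Values stood outside their group in 14 of 80 groups of array measures (17.5%) and in 8 of 97 groups of gene values (8.25%). The rule would flag about 1 in 20 groups of normally distributed, independent values. Some measures were counts, and measures of the same array are not independent, so these shares cannot be set against that rate.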

How the results depend on the processing

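The alternatives that left out the second scan day, the noisiest array, pigs 26 and 32 or single arrays were chosen only after the result was seen. All named genes past the threshold (23, 13 and 1 for the diets, 24 for the tissues) kept their direction, on the probe that stood for the gene, in every alternative run for them, single arrays being left out for diets only, but many calls were lost. For spray dried plasma protein 6 of 23 in jejunum and 10 of 13 in ileum passed with no detection filter, and 9 and 2 with only the 2 diets. With single arrays left out CHRM1 passed in 2 of 14 fits and UGP2 in 3 of 14 in jejunum, and CYP2B22 in 3 of 15 in ileum. The cause of the moves below was not tested. With normexp background correction the counts were 236 for spray dried plasma protein in jejunum, 53 for the F test in jejunum and 0 for the rapeseed meal tissue difference, and the median of all genes for the wheat gluten meal tissue difference moved from 0.0013 to -0.11. With quantile normalisation they were 63 for spray dried plasma protein and 1 for wheat gluten meal in ileum and 13 for the plasma protein tissue difference. With no detection filter they were 84 for spray dried plasma protein and 3 for the F test in jejunum, and in ileum 1 for black soldier fly, 18 for spray dried plasma protein, 1 for rapeseed meal, 2 for wheat gluten meal and 36 for the F test, with 0 for the plasma protein tissue difference. With every probe on its own they were 71 for spray dried plasma protein and 132 for the F test in ileum and 0 for the plasma protein tissue difference. A fixed block for the slide gave 1 for black soldier fly, 941 for spray dried plasma protein and 106 for the F test in jejunum, and 59, 1 and 35 for spray dried plasma protein, wheat gluten meal and the F test in ileum. The same block gave 2468 between tissues and 28 for the plasma protein tissue difference. Array weights gave 294 for the F test in jejunum, 9 for wheat gluten meal in ileum and 12 for the plasma protein tissue difference, and a floor on low signals gave 0 for the rapeseed meal tissue difference. With only the arrays of the 2 diets spray dried plasma protein had 198 in jejunum and 10 in ileum, and wheat gluten meal had 0 in ileum. Without the second scan day the counts were 13 for spray dried plasma protein and 0 for the F test in jejunum, 0 for wheat gluten meal and 37 for the F test in ileum, and 0 for the plasma protein tissue difference. Without pigs 26 and 32 they were 1 for rapeseed meal and 36 for the F test in jejunum, and 3 for rapeseed meal and 2 for wheat gluten meal in ileum. Of 118 gene list tests past the threshold 5 passed with an estimated correlation, 99 with the slide as a block and 95 with quantile normalisation.

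With the pig as a block the tissue differences numbered 14 for spray dried plasma protein, 6 of the 7 shared, and 1 for wheat gluten meal. Of 49 list calls 46 held with the pairing. Those lost were the tissue differences of the unfolded protein response with spray dried plasma protein (adjusted p = 0.0823), T and NK cells with rapeseed meal (0.0586) and lipid absorption with wheat gluten meal (0.0848).

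With single arrays left out, spray dried plasma protein gave 33 to 755 in jejunum. Its pigs 25 (33), 31 (47), 36 (182), 43 (755) and 6 (632) and soybean meal pigs 15 (70), 29 (62), 39 (126), 42 (97) and 8 (157) moved the count over 1.5 times. In ileum it gave 7 to 79, moved by its pigs 17 (7), 25 (11), 31 (19), 36 (79) and 4 (65) and soybean meal pigs 15 (12), 19 (24), 2 (9) and 21 (19). Wheat gluten meal in ileum gave 0 to 25, moved by its pigs 14 (1), 16 (0), 23 (10), 26 (2), 37 (0), 46 (1), 5 (8) and 7 (1) and soybean meal pigs 15 (25), 19 (3), 2 (0), 21 (0), 29 (0), 39 (0) and 42 (1).

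Sign changes among 572 values of named genes included, in jejunum with rapeseed meal, CEBPB at -0.065 with normexp and KLK1 at -0.080 with normexp, -0.049 with quantile normalisation, -0.091 with the slide as a block and -0.029 in the series matrix. JUN in jejunum with black soldier fly was -0.040 with the slide as a block, and the RETNLB tissue difference with black soldier fly 0.17 without the second scan day. The series matrix was not run for tissue comparisons, because its tissues were normalised separately. The planned mean spot signal was absent from the files and the median spot signal replaced it.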

Other observations

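The choice of genes below was made only after the result was seen. CYP1A1 had positive values with black soldier fly, at 2.29 ± 0.98 in jejunum and 2.27 ± 1.03 in ileum, and lay above the soybean meal mean in 8 of 8 pigs in ileum (adjusted p = 1.00 in limma). MT1A averaged 5.13 in jejunum with wheat gluten meal, 4.11 with spray dried plasma protein and 3.25 with soybean meal. In ileum wheat gluten meal and spray dried plasma protein averaged 5.87 and 6.30 (SD 1.26 and 0.72). These 2 diets were not tested against each other, so a difference in their order between tissues was not tested. In the tissue by diet tests the rapeseed meal effect on lipid absorption genes was shifted up in ileum relative to jejunum, with 11 of 12 positive (0.00137, and adjusted p = 0.285 with an estimated correlation). The black soldier fly effect on heat shock and immediate early genes was shifted down in ileum relative to jejunum, with 8 of 9 negative and DNAJB1 at -0.51 ± 0.18 (4.59e-04, and adjusted p = 0.123 with an estimated correlation). Against soybean meal DNAJB1 stood at 0.41 in jejunum and -0.10 in ileum. The list was positive on 5 of 5 slides in jejunum (0.0038 to 0.24).

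Each comparison was set against 99 other splits of the same arrays, and the number of the 100 splits with at least as many features past the threshold, the real one included, is given with the real count and the highest other. Only features without missing values entered (22625 in jejunum, 22433 in ileum and 23328 over both), so real counts differ slightly from those of the full fits. In jejunum it was 1 for spray dried plasma protein (377, highest other 2), 100 for black soldier fly (0 and 46), 100 for rapeseed meal (0 and 1), 100 for wheat gluten meal (0 and 1) and 2 for the F test (21 and 442). In ileum it was 4 for spray dried plasma protein (37 and 225), 1 for wheat gluten meal (5 and 1), 100 for black soldier fly (0 and 1), 100 for rapeseed meal (0 and 1180) and 1 for the F test (51 and 2). Between tissues it was 1 (15626 and 8111, the latter with the tissues of 11 pigs swapped), and for the tissue differences 2 for spray dried plasma protein (7 and 486), 4 for rapeseed meal (1 and 50), 100 for black soldier fly (0 and 110) and 100 for wheat gluten meal (0 and 4). Where features passed, the real count was reached by few splits (1 to 4 of 100, the real one included). No allowance was made for the number of comparisons, and the splits were drawn without regard to slides, so chance was not excluded. For wheat gluten meal in ileum 1 of the 5 features passed with the slide as a block, so the splits do not settle the part of the slides there. Where the real count was 0 every split has as many, so 100 was fixed beforehand and says nothing about chance.

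Splits that called several times the real count were checked for how closely they followed the slides, the only structure of the samples examined. The highest split of the F test in jejunum followed the slides more than any other draw (association 0.559, median 0.428), and with the slide as a block 106 features passed there. The highest split of the plasma protein tissue difference also followed them (0.807, median 0.535), where the slide block gave 28 features. So did that of the wheat gluten meal tissue difference (0.935, median 0.629), where the slide block gave 0. Of the 99 other splits, 1, 3 and 2 were at least as slide-bound as these, the highest splits themselves included. The remaining high splits were no more slide-bound than many draws. For spray dried plasma protein in ileum the association was 0.594 (42 of the 99 splits as high) and for rapeseed meal in ileum 0.646 (21). It was 0.736 (26) for black soldier fly in jejunum and 0.654 (44) for the black soldier fly tissue difference. With the slide as a block 59, 0, 1 and 0 features passed in these comparisons, in this order. For the rapeseed meal tissue difference the association was 0.354, below the median of 0.540, with all 99 splits at least as high. The first principal component held 21.9% of the variance in jejunum and 14.7% in ileum, and the slide accounted for 91.6% and 55.6% of it.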
